A study of Homo sapiens with 24 samples.

How the data were processed

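Total RNA was extracted with Trizol from HL60 derivatives grown in RPMI1640 with 10% fetal calf serum, and biotin-labelled cRNA was made from 100 ng of it with the GeneChip 3'IVT Express kit, per the labels' protocols. One derivative stably carried an shRNA against USP2 and the other a control shRNA. Both were treated with PMA for 0, 1, 2 or 3 days, and 3 Affymetrix U133 Plus 2.0 arrays were made per group, 24 in all. The PMA dose stands as 30 nM in the treatment protocol and as 32 nM in the sample characteristics, and neither was preferred here. Each sample was assigned to its group by its title and characteristics, and replicate numbers were taken from the titles.

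The deposited values are linear intensities, 1 per probe set and array, made with GCOS per the submitters' processing notes. The version and algorithm settings are not given in the sources used here. Without the highest and lowest 2% of probe sets, every array had a mean intensity of 500.1, as arrays have after global scaling by the authors, while array medians ran from 66.8 to 91.8. Detection calls were not used here, so signal was judged against the median of its array. The number of arrays limits the precision.

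Of 54675 probe sets, 62 controls were left out. In the annotation of the platform, which can be old, 41091 of the others named 1 gene, 1801 several and 11721 none. Symbols of 41037 probe sets were updated through the gene identifier, with a RefSeq gene table of assembly GRCh38.p14 used for names only, and 54 kept the old symbol. Values were taken as log2(intensity + 16), a scale that understates changes of dim genes. A probe set was kept if it lay above the array median on at least 3 of 24 arrays, which left 35464. Of these, 27951 named 1 gene, and the one with the highest mean log2 value over the 24 arrays was used for each of 14571 genes, of which 7128 had several. Where the other probe sets of a named gene went the other way, this is stated. A gene below the array median on all 3 arrays of a group has only a bound there, and its fold is given as "at least". This bound is the mean of the brighter group over the mean of, per array, the higher of the array median and the gene's own value. No fold is given where this is under 1 or both groups are below. Some genes of the lists have no entry in the annotation used and were not analysed here.

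Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided) in 1 fit of 8 group means over 24 arrays with 16 residual degrees of freedom. Benjamini-Hochberg adjustment covered all genes, with a threshold of 0.05. Comparisons were USP2 shRNA against control shRNA on each day and averaged over the 4 times, each PMA day against day 0 in each derivative, and the difference of the PMA responses as an F test of 3 interaction terms. The comparisons of the derivatives on different days use different arrays, while the PMA days of a derivative share its day 0 arrays. The USP2 level over the 4 times was tested with an exact permutation test stratified by day (160000 permutations). On simulated data for the day 2 comparison, with 50 genes changed at each size among 14571, the fit recovered 30% at a log2 change of 0.5, 60% at 1, 70% at 1.5 and 72% at 2, with 3 false calls.

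The samples, tests, alternatives, named-gene rule and 21 gene lists were fixed before the data were examined. The rule named USP2, and among called genes whose groups did not overlap the 4 largest rises and 4 largest falls between the derivatives per day. It named 10 and 10 for the mean of 4 times among called genes with 1 direction at all of them, 6 and 6 for PMA per day in control cells, 4 and 4 at day 3 in USP2 shRNA cells, and 5 and 5 for the interaction. For each list described it took up to 4 called members with the largest change and up to 2 that did not pass. Gene names outside this rule are said to be so. The lists cover macrophage markers, promyelocyte and granule genes, cell cycle, MYC and ribosome biogenesis, cytokines and chemokines, NF-kappaB feedback, adipose inflammation and phagocyte oxidase. Further lists are lysosome, matrix and adhesion, p53 targets, circadian clock, deubiquitinases, stress and amino acid response, fatty acid synthesis, sterol synthesis, interferon response and immediate-early AP-1 genes. Markers of erythroid and megakaryocytic, lymphoid, and epithelial and fibroblast cells stand for cell types other than the one studied. They hold 423 genes, of which some were on 2 lists. Of these genes 343 were measured, 37 were dim, 15 had probe sets of several genes and 28 were not listed. FABP4 and TNF were put on the adipose list with knowledge of the study's subject. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 21 lists of a comparison, and again with an estimated correlation and with fry (statmod 1.5.0 was installed). Counts adjusted over the list alone stand beside those over all genes.

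Alternatives were offsets of 1 and 64, quantile normalization, median centring, no filter, a filter of 12 arrays, the mean over the probe sets of a gene, no trend, array weights, only the groups compared, the replicate number as a block, and leaving out each array in turn. The ratio of 3' to 5' ACTB probe sets as a covariate, and the list tests without control day 1 replicate 3, were added after the data had been seen. For the share of cells left as at day 0, a first test compared the median over 33 abundant genes (1.26%) with the share needed (2.77%) and left the explanation open. The 33 held some of the called genes that set the share needed. A test on the lowest of the 33 genes, with bounds set after its values were seen, was then used. Figures were drawn with matplotlib 3.10.9.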

Results

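HL60 is a human promyelocytic leukaemia cell line that adheres and takes on macrophage features when treated with phorbol 12-myristate 13-acetate (PMA), an activator of protein kinase C. The data are 24 Affymetrix U133 Plus 2.0 arrays of total RNA from 2 HL60 derivatives. One derivative stably expressed a short hairpin RNA (shRNA) against USP2, a ubiquitin-specific protease that removes ubiquitin from other proteins, and the other a control shRNA. Each was sampled after 0, 1, 2 and 3 days of PMA, with 3 arrays per group and 8 groups. The PMA dose is given as 30 nM in the treatment protocol and as 32 nM in the sample labels. Gene values are deposited linear intensities, given as mean ± SD over 3 arrays, and differences are on the log2(intensity + 16) scale ± SE from limma. Spearman correlations over probe sets were 0.884 to 0.902 between arrays of one group and 0.878 to 0.898 between derivatives on the same day. They were 0.804 to 0.829 between day 0 and PMA-treated arrays, within and across the derivatives. The first principal component carried 61.4% of the variance. The labels do not say that replicates were separate cultures, so p-values measure the spread between these arrays, which may be technical. The study holds 1 derivative per shRNA, so a difference between the derivatives is a difference between 2 cell populations.

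USP2 itself was lower in the derivative labelled with USP2 shRNA at each PMA day. With the 1 of its 4 probe sets that had the highest mean log2 level over the 24 arrays, its level in USP2 shRNA cells was 461 ± 90.5 against 1222 ± 72.6 in control cells at day 1, 669 ± 21.3 against 1600.2 ± 111 at day 2 and 611 ± 15.7 against 1264 ± 113 at day 3. In every comparison of the derivatives, the USP2 shRNA cells are given first. At day 0 the levels were 82.2 ± 20 against 116 ± 8.67 (adjusted p = 0.166), close to the array medians of 66.8 to 91.8. PMA raised USP2 in both derivatives, by 3.23 ± 0.14 at day 1 in control cells and 2.28 ± 0.14 in USP2 shRNA cells on the log2 scale. Over the 4 times the difference averaged -1.03 (exact permutation test stratified by day, two-sided, p = 1.25e-05, the smallest that 160000 permutations can give). Within a day the smallest possible exact p is 0.1, and this probe set reached it on all 4 days. A further bright probe set differed by -1.30 (exact p = 6.25e-05) and a dim one by -0.73 (exact p = 0.00945). The remaining dim probe set, with group means of 6.05 to 61.1, went the other way, by 0.44 (exact p = 0.243).

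**Figure D1:**
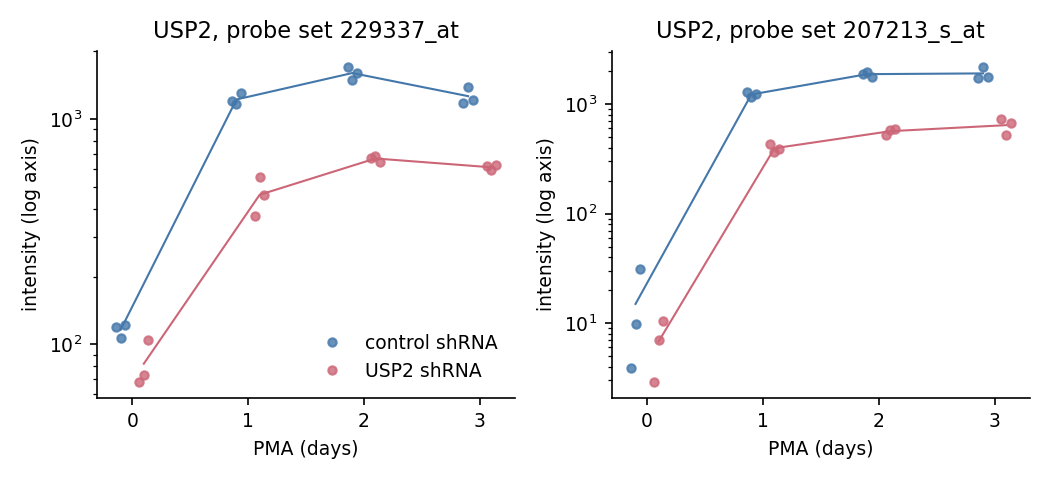
USP2 intensity (log axis) against days of PMA for 2 probe sets, with 1 point per array and lines through the means of 3 arrays. From day 1 on, every USP2 shRNA array lies below every control array, for example at 372 to 553 against 1165 to 1303 at day 1 for the probe set with the highest mean log2 level, in the left panel.

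In control cells 8008 of 14571 genes passed an adjusted p of 0.05 at day 1 of PMA, 3584 higher and 4424 lower, and 4366 of them differed by at least 2-fold. At day 2 the counts were 4119 higher and 4185 lower, and at day 3 4036 and 4150. Most of the genes with the largest rises were below the array median on all 3 arrays at day 0, so their folds are lower bounds. PNOC, the precursor of the neuropeptide nociceptin, reached 27636 ± 5208 at day 1, at least 376-fold above day 0. EMP1, a membrane protein, rose at least 591-fold, TFPI2, a serine protease inhibitor, at least 190.1-fold, RGS1, a regulator of G protein signalling, at least 351-fold and INHBA, the activin A subunit, at least 265-fold. SPP1, which encodes osteopontin, went from 54.7 ± 25.6 to 41688 ± 4432. At day 2 A2M, a protease inhibitor, DCSTAMP, a protein of cell fusion in osteoclasts, and GPC4, a glypican, rose at least 199-, 314- and 226-fold. At day 3 CD52 rose at least 593-fold and CD9, a tetraspanin, reached 31994 ± 1558 against 53.5 ± 43.5. Other kept probe sets of A2M (-0.12) and CD9 (-1.08) went the other way at these days.

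Genes of the starting promyelocyte fell. ELANE, PRTN3 and CTSG, the serine proteases of azurophil granules, went from 16709.5 ± 358 to 15.6 ± 7.89, from 9113 ± 1010.3 to 21.4 ± 13.5 and from 15769 ± 1579.8 to 106 ± 46.5 at day 1. S100A8, a subunit of calprotectin, went to 114 ± 7.24 from 14593 ± 801. SERPINB10 and CACNA2D3 fell at least 79.6- and 32-fold. By day 3 MS4A3, a membrane protein of myeloid progenitors, was at 66.1 ± 45.3 against 29126 ± 1897, RNASE2, a ribonuclease of eosinophil granules, at 46.9 ± 31.9 against 9266 ± 603 and MYB, a transcription factor of progenitors, at 99.1 ± 37.7 against 16956 ± 740.0. Of 14 measured genes on the promyelocyte and granule list, 12 fell on each of the 3 days (12 adjusted over the list alone). CAMP and LCN2 did not pass the test on any of these days, with LCN2 at 58.5 ± 21.4 against 69.1 ± 28.1 at day 3.

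Proliferation genes fell as well. Of 30 cell cycle genes, 29 fell at day 1, 27 at day 2 and 28 at day 3 (30, 28 and 29 adjusted over the list alone). TYMS, thymidylate synthase, went to 414 ± 57.9 against 33397 ± 2174 and CDK1, the mitotic kinase, to 193 ± 41.9 against 12196 ± 633 at day 1. The mean log2 level of the list in control cells was 11.87 ± 0.03 at day 0, 7.90 ± 0.01 at day 1, 9.19 ± 0.06 at day 2 and 9.64 ± 0.04 at day 3 (SD, n = 3). Of 17 MYC and ribosome biogenesis genes, 16 fell on each day (16 adjusted over the list alone), with MYC at 1318 ± 83.2 against 46840.5 ± 7627 at day 3.

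Lists of the macrophage state rose. Of 24 lysosome genes, 19, 22 and 20 rose on days 1, 2 and 3 (the same numbers adjusted over the list alone), among them CTSB and CTSL, cathepsins, at 28528 ± 808 against 2735 ± 225 and 12403 ± 1568 against 1341 ± 3.03 at day 3. Of 19 matrix and adhesion genes, 14 rose on each day (14 adjusted over the list alone), including MMP9, a gelatinase, at 49562 ± 7882 against 163 ± 16 at day 1 and MMP7, matrilysin, at 6187 ± 388 against 65.7 ± 18.1 at day 3. Of 21 macrophage markers, 12, 12 and 11 rose and 2, 4 and 3 fell (the same numbers adjusted over the list alone). ITGAM, the CD11b integrin chain, reached 17110.4 ± 1361 at day 3, while CD80 was at 41.2 ± 26.1 against 76.6 ± 33.8. The cytokine and chemokine list had 14, 11 and 12 of 23 members higher (14, 11 and 13 adjusted over the list alone), such as IL1B at 41873 ± 4359 against 235 ± 23 and CCL20 at 4579 ± 564 against 33.6 ± 32.5 at day 1. CXCL10 did not pass at day 1 (58.3 ± 30.4 against 24.4 ± 29.7). All 18 immediate-early and AP-1 genes were higher at day 1, 15 at day 2 and 12 at day 3 (the same adjusted over the list alone), with EGR1, an early growth response factor, at 4035 ± 333 against 64.4 ± 4.08 at day 1. NF-kappaB feedback genes were higher in 10, 9 and 10 of 15 cases (the same adjusted over the list alone), with BCL2A1 at 15848 ± 1111 against 386 ± 29.6 at day 3. Of 16 genes on the adipose inflammation list, 9, 10 and 10 rose and 2, 5 and 5 fell (the same adjusted over the list alone), with LGALS3, a galectin, at 63932 ± 9890.0 against 714 ± 58.5 at day 3.

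These lists, namely granule, cell cycle, MYC, lysosome, matrix, macrophage, cytokine, immediate-early, NF-kappaB and adipose, passed camera on each day in control cells, and the calls held with an estimated correlation (highest adjusted p = 0.023). Sterol synthesis passed at days 1 and 2 (adjusted p = 0.022 and 0.0043 with an estimated correlation), with 7 and 11 of 13 genes higher (9 and 11 adjusted over the list alone). At day 3 its adjusted p was 0.0519. Interferon response passed at day 3, with 13 of 17 genes higher and 2 lower (the same adjusted over the list alone, adjusted p = 0.0303 with an estimated correlation). IFI6 was at 1558 ± 78.7 against 79.4 ± 24.7 and HERC5 at 135 ± 65.9 against 1023 ± 63.3 at that time. Its call at day 2 was lost (adjusted p = 0.0866 with an estimated correlation). The stress and amino acid response list, with 13 of 19 genes lower at day 3 (13 adjusted over the list alone), lost its call there too (adjusted p = 0.0659 with an estimated correlation). No camera call was made on any day for the circadian clock, deubiquitinase, fatty acid synthesis, p53 target and phagocyte oxidase lists or for markers of erythroid and megakaryocytic, lymphoid, and epithelial and fibroblast cells. At day 3 genes of these lists went both ways, with 5 higher and 5 lower of 13 circadian clock genes, 10 and 11 of 25 deubiquitinases and 4 and 5 of 13 fatty acid synthesis genes. The counts were 8 and 7 of 18 p53 targets (10 and 7 adjusted over the list alone, the other lists unchanged in number) and 3 and 3 of 6 phagocyte oxidase genes. Of the other cell type markers PPBP, a platelet chemokine also made by monocytes, reached 2885 ± 1657 against 13.8 ± 20.3 at day 3, and PDGFRB was at 369 ± 40 against 13.1 ± 13.1 at day 1. The ratio of 3' to 5' ACTB control probe sets, a sign of RNA quality and priming, moved with time. In control cells its log2 went from 1.56 ± 0.04 at day 0 to 1.16 ± 0.27, 1.69 ± 0.09 and 2.30 ± 0.19 (SD, n = 3) at days 1 to 3. The median of all genes moved by -0.10 at day 1 and by 0.01 at day 3 as deposited, and by -0.15 at day 3 after median centring.

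USP2 shRNA cells responded to PMA with 8110, 8349 and 8306 called genes at days 1, 2 and 3, of which 3758, 4144 and 4162 were higher. After median centring 3630 were higher and 4718 lower at day 3, and 3452 and 4831 in control cells. At day 3 the largest rises were those of CD9, RGS1, FAM20C, a secretory pathway kinase, and DCSTAMP, at least 479-, 429-, 190.5- and 289-fold. Named for the largest falls on this scale were ELANE, MYB and PRTN3, at least 230.5-, 204- and 132-fold, and MS4A3, to 103 ± 39 against 29523 ± 1018 at day 0. One of 3 other FAM20C probe sets went the other way (-0.97). All 30 cell cycle genes and 12 of 14 granule genes were lower at day 3 (30 and 13 adjusted over the list alone), and 21 of 24 lysosome, 14 of 19 matrix and 11 of 21 macrophage genes were higher (the same adjusted over the list alone). These 5 lists passed camera at day 3 with an estimated correlation, with a highest adjusted p of 0.0145. So did sterol synthesis at days 1 and 2, with 10 of 13 genes higher each time (10 adjusted over the list alone, adjusted p = 0.0136 and 0.00505), and interferon response at day 3, with 13 of 17 higher (13 adjusted over the list alone, adjusted p = 0.0257). The stress and amino acid response list, with 12 of 19 lower at day 3 (12 adjusted over the list alone), lost its call (adjusted p = 0.0818 with an estimated correlation). Log2 changes in the 2 derivatives, which share no arrays, correlated across genes with r of 0.937, 0.942 and 0.937 at days 1 to 3, where genes are not independent replicates. At these days 7024, 7397 and 7277 genes were called in the same direction in both, against 2246, 2379 and 2333 for independent lists, and 10, 8 and 10 in opposite directions. Both derivatives share the estimate of a gene's spread, so independent lists are not a fair baseline.

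Before PMA, 141 genes differed between the derivatives, 65 higher and 76 lower in USP2 shRNA cells. VAT1L was at 629.9 ± 123 against 163 ± 2.95 (log2 1.83 ± 0.14, adjusted p = 1.61e-08) and S100P, a calcium-binding protein, at 1993 ± 76.1 against 728 ± 13.4. APOC1, an apolipoprotein, was higher by at least 1.05-fold and GPRC5C, an orphan receptor, was at 72.1 ± 24 against 13.6 ± 4.31, with the control arrays below the array median. Lower in USP2 shRNA cells were the pseudogene ANXA2P1, TSKU, a secreted leucine-rich repeat protein, and CATSPER1, a sperm calcium channel subunit, by at least 1.52-, 1.35- and 1.65-fold, and NHSL1 (4.69 ± 3.14 against 50.3 ± 13.1), which lay below the array median in both. Among list members, VIM, which encodes vimentin, was lower at 6880.1 ± 201 against 9742 ± 998 and CTSH, cathepsin H, at 155 ± 38.1 against 289 ± 40.7. CD36, a scavenger receptor, was lower at 100.4 ± 16.8 against 193 ± 17.6, ME1, malic enzyme, higher at 1070.3 ± 64.3 against 681 ± 110.1 and CXCL8 higher at 8638 ± 812 against 6359 ± 535. Of 21 lists, 4 passed camera at day 0, and each call was lost with an estimated correlation. These were the cell cycle list (median 0.14, 0 members called, adjusted p = 0.128 with an estimated correlation) and the stress response list (1 of 19 higher, 2 adjusted over the list alone, adjusted p = 0.0532). The others were fatty acid synthesis (1 of 13 higher, 2 adjusted over the list alone, adjusted p = 0.0532) and matrix and adhesion (1 of 19 lower, 5 adjusted over the list alone, adjusted p = 0.0899). The count fell to 90 with an offset of 64, to 80 with the mean over probe sets or without the trend, to 24 with only the 6 arrays concerned and to 89 without control day 0 replicate 2. Median centring gave 73 higher and 50 lower of 123. Leaving out 1 array ended the calls of 6 of the 15 called genes named for this day, whose highest adjusted p was then 0.0614 for APOC1, 0.0963 for CATSPER1, 0.0957 for CXCL8, 0.117 for GPRC5C, 0.0632 for S100P and 0.139 for TSKU.

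At day 1 of PMA, 386 genes differed, 247 higher and 139 lower in USP2 shRNA cells. Some genes of the promyelocyte were higher, although PMA had lowered them in both derivatives. Of 14 measured members of the granule list, 5 were higher and 0 lower (5 adjusted over the list alone, median 0.52). They were MS4A3 at 1396 ± 11.2 against 359.8 ± 21.6, MYB at 1089.7 ± 202 against 270.3 ± 9.36 and PRG2, a granule protein of eosinophils, at 2498 ± 377 against 849.9 ± 103. The others were RNASE2 at 358 ± 27.7 against 112 ± 27.2 and CEBPE, a granulocyte transcription factor named after its value was seen, at 266 ± 42.1 against 152 ± 54.9. ELANE did not pass, at 59 ± 54.8 against 15.6 ± 7.89. Further members that did not pass, named after their values were seen, were CFD (484 against 324) and CTSG (147 against 106). MPO (2219 against 2086), SERPINB10 (46.2 against 46.3) and PRTN3 (12.8 against 21.4) did not pass either, so the list did not move as a whole. Of 30 cell cycle genes, 10 were higher and 0 lower (13 and 1 adjusted over the list alone, median 0.49). Among them were CDK1 at 546 ± 100.1 against 193 ± 41.9, and TOP2A, a topoisomerase, at 303 ± 33.7 against 137 ± 17, with BIRC5, survivin, at 140.4 ± 11.1 against 35.7 ± 13.7 and KIF11, a spindle kinesin, at 107 ± 26.9 against 40.3 ± 15.9. Both lists passed camera, with adjusted p = 0.000915 for granule genes and 0.000489 for cell cycle genes with an estimated correlation. Without control day 1 replicate 3 the granule median was 0.40 and the cell cycle median 0.31, with 10 cell cycle genes called higher and adjusted p of 0.009 and 0.005 with an estimated correlation.

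Beyond these lists, CCL2, the monocyte chemoattractant protein, was at 935 ± 84.2 against 169 ± 47.5 at day 1 (log2 2.39 ± 0.44, adjusted p = 0.00182). FABP4, the fatty acid binding protein of adipocytes and macrophages, was at 6871 ± 794 against 1904 ± 278 (log2 1.85 ± 0.18, adjusted p = 3.11e-07), FN1, fibronectin, at 1559.5 ± 133 against 529 ± 197 and MMP7 at 8729.7 ± 801 against 3775 ± 992. Both CCL2 and FABP4 belong to the adipose inflammation list, on which FABP4 was placed knowing the study, and which had 2 of 16 members higher and 1 lower (VEGFA, 2777 ± 85.4 against 3814 ± 129) with no camera call (adjusted p = 0.111). TNNT1, a troponin T, LYRM9 and RHOH were higher by at least 1.89-, 1.49- and 1.88-fold. Lower by at least 1.25-, 2.06-, 2.4- and 1.7-fold were SLC51B, an organic solute transporter subunit, HK3, a hexokinase, LINC00491 and FBXO2, an F-box protein. Macrophage markers went both ways, with TLR2 higher at 3026 ± 498 against 1825 ± 193 and CD36 and CLEC7A, the beta-glucan receptor, lower at 8687 ± 798 against 13373 ± 744 and 1326 ± 103 against 2115 ± 175. The phagocyte oxidase list had 2 of 6 genes higher, CYBB at 15426 ± 1404 against 9730 ± 796 and NCF4 at 1167 ± 49 against 859.9 ± 107 (4 adjusted over the list alone), and its call was lost (adjusted p = 0.0946 with an estimated correlation, 0.0125 without control day 1 replicate 3). That of the MYC and ribosome list, with 1 gene higher and 2 lower of 17 (the same adjusted over the list alone), was lost too (adjusted p = 0.134 with an estimated correlation). The count of 386 depends on single arrays. It was 204 without control day 1 replicate 2, 223 without control replicate 1, 255 and 257 without USP2 shRNA replicates 1 and 2, and 1109 without control replicate 3. It was 236 with the mean over probe sets, 1438 with array weights and 123 with only the 6 arrays concerned. Of the 34 called genes named for this day, 10 lost the call without 1 array, with a highest adjusted p of 0.269 for CEBPE, 0.105 for CYLD, 0.105 for FBXO2, 0.0581 for KIF11, 0.147 for LINC00491, 0.1 for MMP7, 0.0678 for PRKACB, 0.1 for RHOH, 0.131 for RNASE2 and 0.116 for TLR2. The call of RNASE2 ended in each of the 6 fits without 1 array.

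At day 2, 296 genes differed, 89 higher and 207 lower, and the cell cycle genes stood on the other side. Of 30, 20 were lower and 0 higher in USP2 shRNA cells (26 lower and 1 higher adjusted over the list alone, median -0.85), with adjusted p = 2.41e-08 with an estimated correlation. TYMS was at 881 ± 72.6 against 3153 ± 339 (log2 -1.82 ± 0.10, adjusted p = 7.13e-12), and BUB1B, a spindle checkpoint kinase, at 228 ± 39.7 against 537 ± 10.7. TOP2A was at 101 ± 10.1 against 253 ± 17.8 and BIRC5 at 89.3 ± 38.1 against 235 ± 6.5. AURKB did not pass, at 19.5 ± 19.2 against 77 ± 37.9. Of the genes with the largest falls outside the list, MYBL2 and FOXM1, transcription factors of the cell cycle, were lower by at least 1.95- and 2.03-fold and CENPM, a centromere protein, was at 52.9 ± 36.2 against 225 ± 27.1. PBX2, a homeobox factor, was at 166 ± 71.2 against 840.2 ± 155, but 1 of its 3 other kept probe sets went the other way (0.87). The mean log2 level of the cell cycle list went from 8.27 ± 0.03 at day 1 to 8.38 ± 0.03 at day 2 in USP2 shRNA cells, and from 7.90 ± 0.01 to 9.19 ± 0.06 in control cells (SD, n = 3).

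Of 23 cytokines and chemokines, 3 were higher at day 2 (3 adjusted over the list alone). They were CXCL8 at 13045 ± 1452 against 7669 ± 98, IL1B at 12679.7 ± 365 against 8983 ± 375 and CCL2, at least 3.03-fold. The call of CCL2 ended in each of the 6 fits without 1 array. TNF did not pass (122 ± 54.4 against 67.3 ± 34.6). This list (adjusted p = 0.0232), the immediate-early list with 1 of 18 higher (5 adjusted over the list alone, adjusted p = 0.00331) and the adipose list with 2 of 16 higher (2 adjusted over the list alone, adjusted p = 0.00676) passed with an estimated correlation. The NF-kappaB feedback list had no camera call (adjusted p = 0.509). The matrix and adhesion list, with 2 of 19 higher (2 higher and 2 lower adjusted over the list alone), lost its call (adjusted p = 0.236 with an estimated correlation). FN1 was at 4450.3 ± 322 against 1558 ± 105 and MMP7 at 6407 ± 911 against 2292 ± 281. FABP4 was at 4529 ± 217 against 1462 ± 259, and BMAL1, a transcription factor of the circadian clock, at 984 ± 122 against 503 ± 43.2. TNNT1 and SLC9A9, an endosomal sodium-proton exchanger, were higher by at least 1.05- and 2.02-fold, and LINC01019 was at 66.8 ± 18.9 against 8.21 ± 3.18. Leaving out 1 array gave counts of 171 and 171 (USP2 shRNA replicates 1 and 3), 191 (USP2 shRNA replicate 2), 183 and 178 (control replicates 1 and 3), and the count was 664 with array weights (257 higher and 407 lower) and 661 with only the 6 arrays concerned (318 higher and 343 lower). The calls of 8 of the 28 called genes named for this day ended without 1 array, at a highest adjusted p of 0.152 for BMAL1, 0.167 for CCL2, 0.109 for HSPA5, 0.19 for LINC01019, 0.0525 for PBX2, 0.158 for TNNT1, 0.072 for USP1 and 0.0622 for USP14. Like that of CCL2, the calls of BMAL1, LINC01019 and TNNT1 ended in each of the 6 fits.

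At day 3, 124 genes differed, 60 higher and 64 lower. FABP4 had the largest rise, at 5550.3 ± 996 against 958 ± 330.3 (log2 2.55 ± 0.18, adjusted p = 1.83e-09), and FABP5, of the same family, was at 20597 ± 1370.4 against 15440.4 ± 98.5. FN1 was at 3624 ± 1369.7 against 1049 ± 183, with 1 of its 4 other kept probe sets close to no difference (-0.03). SIGLEC9, a sialic acid-binding lectin, and AEN, a nuclease regulated by p53, were higher by at least 1.05- and 1.31-fold. Cell cycle genes were still lower in 5 of 30 cases and higher in 0 (16 lower adjusted over the list alone, median -0.42, adjusted p = 8.74e-06 with an estimated correlation). NUSAP1, a spindle protein, was at 845 ± 88.2 against 1422 ± 99.4 and TYMS at 2657 ± 236 against 4534 ± 339. BUB1B at 561 ± 81.1 against 1063 ± 125 did not pass. MYBL2 was at 51.2 ± 40.5 against 201 ± 41.7 and KIFC1, a spindle kinesin, at 49.7 ± 48.1 against 265 ± 21.2. TSPAN18 was lower by at least 1.24-fold and ITPR3, an inositol trisphosphate receptor, at 57.4 ± 69.5 against 232 ± 12.1, with 1 of 2 other ITPR3 probe sets at 0.05. The granule list had 0 members higher and 1 lower, MYB at 37.1 ± 26.1 against 99.1 ± 37.7, named after its value was seen (2 lower adjusted over the list alone). Immediate-early genes were higher in 3 of 18 cases (KLF4, 365 ± 59.9 against 222 ± 46.7, EGR1, 255 ± 46.9 against 136 ± 57.8, and MAFF, 8312 ± 181 against 6104 ± 287; 4 adjusted over the list alone), with no camera call (adjusted p = 0.275). LIPA, the lysosomal acid lipase, was higher at 6331 ± 598 against 3925 ± 175 and CTSH lower at 1582 ± 78.7 against 2279 ± 100. The phagocyte oxidase list, with 1 of 6 higher (1 adjusted over the list alone), CYBB at 8017 ± 263 against 6041 ± 391, lost its call (adjusted p = 0.308 with an estimated correlation). The count fell to 66 and 74 without control replicates 1 and 3, to 67 and 71 without USP2 shRNA replicates 1 and 2, to 71 with the mean over probe sets and to 49 with only the 6 arrays concerned. Median centring gave 73 higher and 33 lower of 106, and quantile normalization 73 higher and 62 lower of 135. Among the 23 called genes named for this day, 12 lost the call without 1 array, with a highest adjusted p of 0.188 for CTSH, 0.119 for CYBB, 0.295 for EGR1, 0.103 for GM2A, 0.126 for ITPR3, 0.105 for KLF4, 0.13 for MAFF, 0.17 for MYB, 0.0799 for MYBL2, 0.138 for NPC2, 0.171 for TSPAN18 and 0.052 for UCHL1. Those of CTSH, MAFF and TSPAN18 were lost in each of the 6 fits.

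**Figure D2:**
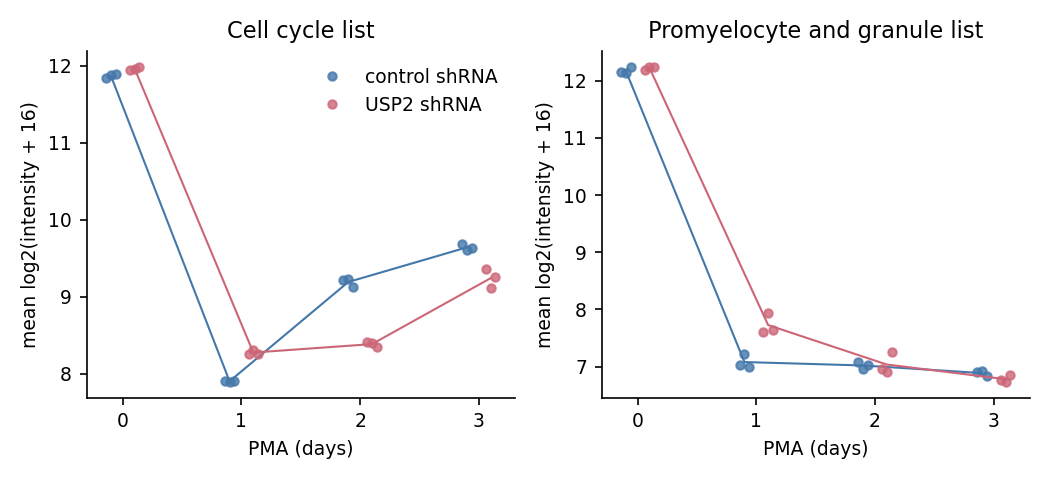
Mean log2(intensity + 16) of the 30 measured cell cycle genes and the 14 measured granule genes against days of PMA, with 1 point per array and lines through the means of 3 arrays. For the cell cycle list the USP2 shRNA cells lie above control cells at day 1 (8.27 against 7.90) and below them at day 2 (8.38 against 9.19) and day 3 (9.24 against 9.64).

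Averaged over the 4 times, 693 genes differed, 367 higher and 326 lower in USP2 shRNA cells, and 9 differed by at least 2-fold on average. Among called genes with 1 direction at all 4 times, those with the largest mean rise were CCL2 (log2 1.34 ± 0.22), C1orf21 (1.07 ± 0.25), RND3 (0.99 ± 0.23), RHEX, a regulator of erythroid cells (0.94 ± 0.10), and MS4A3 (0.93 ± 0.15). They were followed by AIG1 (0.87 ± 0.20), TIAM1, an exchange factor for Rac (0.84 ± 0.19), SIGLEC9 (0.84 ± 0.18), SPATS2L (0.82 ± 0.09) and GPRC5C (0.80 ± 0.17). Both other C1orf21 probe sets (-0.05 and -0.14) and the other probe sets of RHEX (-0.37) and GPRC5C (-0.06) did not share the rise. Those with the largest mean fall were CDR2L (-1.36 ± 0.19), ITPR3 (-1.27 ± 0.23), USP2 (-1.03 ± 0.07), the olfactory receptor OR1E1 (-1.0 ± 0.28) and TARP (-0.98 ± 0.25). They were followed by CASC17 (-0.97 ± 0.27), LRP11 (-0.92 ± 0.16), FAP, fibroblast activation protein (-0.92 ± 0.16), CDC25A, a cell cycle phosphatase (-0.92 ± 0.25), and AJAP1 (-0.92 ± 0.25). AJAP1 lay below the array median on all USP2 shRNA arrays, so the size of its fall depends on the offset of 16. UCHL1, another deubiquitinase, was higher (log2 0.80 ± 0.08, adjusted p = 2.56e-07), as was BMAL1 (0.78 ± 0.12, adjusted p = 0.000144), while CD36 (-0.54 ± 0.05) and MYC (-0.25 ± 0.05) were lower. For the cell cycle list this average joins opposite signs, with a mean log2 level of 8.27 against 7.90 at day 1 and 8.38 against 9.19 at day 2. The list (8 of 30 lower and 1 higher, 14 and 1 adjusted over the list alone, adjusted p = 0.000833) passed with an estimated correlation. So did the adipose list (3 of 16 higher, 3 adjusted over the list alone, adjusted p = 0.0114) and the immediate-early list (4 of 18 higher, 5 adjusted over the list alone, adjusted p = 0.0123). The phagocyte oxidase list, with 1 of 6 higher (1 adjusted over the list alone), lost its call (adjusted p = 0.239 with an estimated correlation). Of the markers of other cell types, PPBP alone was called (0.73 ± 0.17), and none of these 3 lists passed camera in any comparison of the derivatives. The count was 1070 without control day 1 replicate 3 and 1233 with array weights. In direction, median centring gave 529 higher and 205 lower of 734, and the mean over probe sets 225 higher and 270 lower of 495. Of the 29 called genes named here, 4 lost the call without 1 array, with a highest adjusted p of 0.066 for AJAP1, 0.0763 for CASC17, 0.0581 for CDC25A and 0.0755 for OR1E1.

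The 4 single-day comparisons share no arrays. Of 14571 genes, 603 were called on 1 day, 103 on 2, 42 on 3 and 3 on all 4. Each of these 3 lost the call of a day without 1 array, CTSH at day 3 in 6 of 6 fits, GM2A at day 3 in 3 and PRKACB at day 1 in 3. They were named after their values were seen and were lower in USP2 shRNA cells each time. The mean log2 difference was -0.70 ± 0.06 for CTSH, -0.45 ± 0.04 for GM2A, the lysosomal activator of GM2 ganglioside breakdown, and -0.42 ± 0.04 for PRKACB, a catalytic subunit of protein kinase A. Days 1 and 2 shared 34 higher and 24 lower genes, and 31 genes were called in opposite directions. Independent lists would share 1.5, 2 and 4.4. Days 2 and 3 shared 24 higher and 35 lower genes, against 0.37 and 0.91, with 0 opposite. The spread of a gene was estimated once for all days. A gene with a low estimate is called more easily on each of them, so independent lists are not a fair baseline.

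**Figure D3:**
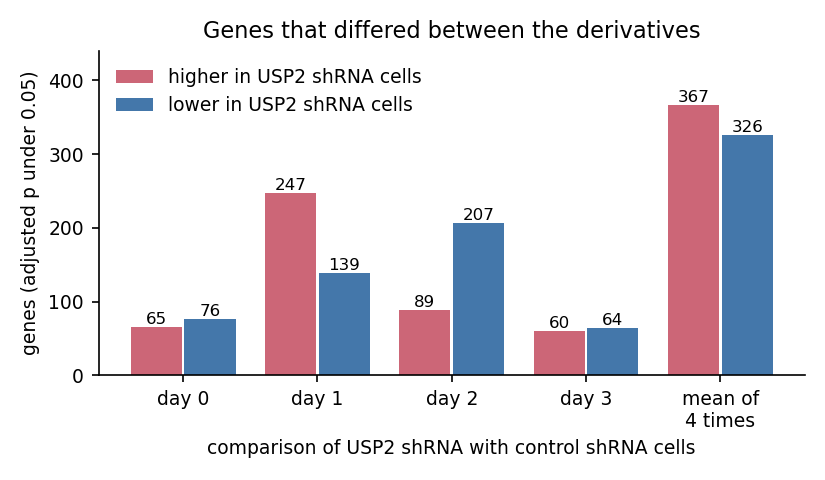
Number of genes with an adjusted p under 0.05 that were higher or lower in USP2 shRNA than in control shRNA cells, on each day and for the mean of 4 times. Day 1 has more higher (247) than lower genes (139) and day 2 more lower (207) than higher ones (89).

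Whether the PMA response differed between the 2 derivatives was tested with the 3 interaction terms together, and 284 genes passed. Of these, 113 had a positive and 171 a negative term at day 3, whether or not that term passed on its own. Over all genes, of the terms that passed on their own, 89 were positive and 43 negative at day 1, 43 and 89 at day 2, and 47 and 26 at day 3. Among the 284 genes, FABP4 had the highest day 3 term (log2 2.73 ± 0.25, adjusted p of the F test = 5.65e-07), followed by RBP4, the retinol-binding protein (2.42 ± 0.44), FN1 (2.32 ± 0.29), AEN (2.07 ± 0.45) and SLC26A11, an anion transporter (1.92 ± 0.24). The lowest terms among them were those of PROC, which encodes protein C (-1.99 ± 0.24), MYBL2 (-1.95 ± 0.51), PLCD3, a phospholipase C (-1.85 ± 0.67), S100P (-1.74 ± 0.44) and VAT1L (-1.65 ± 0.20). A group behind the terms of FABP4, RBP4, AEN, SLC26A11, PROC and PLCD3 lay below the array median on all 3 arrays. The size of these terms therefore depends on the offset of 16 and gives no order. The day 3 terms of MYBL2, PLCD3 and S100P did not pass on their own (adjusted p = 0.0985, 0.315 and 0.0853). For USP2 itself the adjusted p of the F test was 0.0318. Of the probe sets of FN1, 1 of 4 others had a day 3 term of -0.19. The count was 187 with the mean over probe sets, 184 without the trend, 608 with array weights and 544 without control day 1 replicate 3. Among the 10 genes named by this test, 2 lost the call without 1 array, with a highest adjusted p of 0.109 for AEN and 0.122 for PLCD3.

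**Figure D4:**
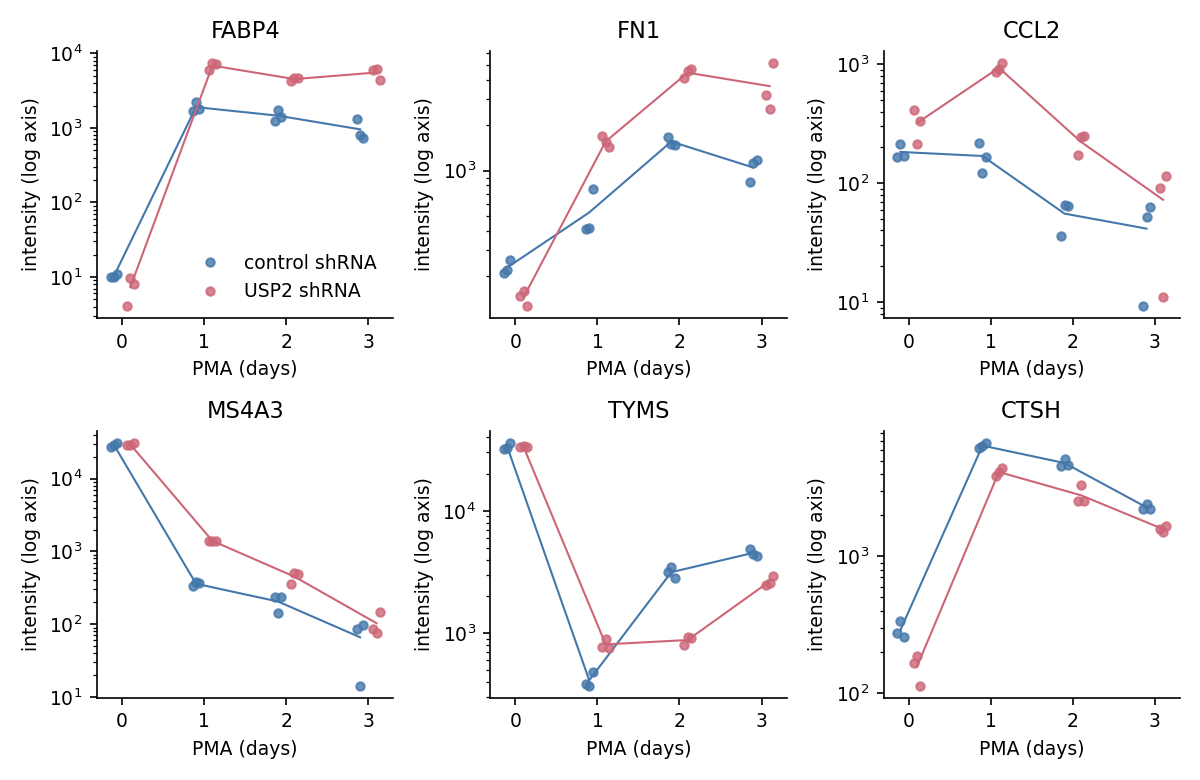
Intensity (log axis) of 6 genes against days of PMA, with 1 point per array and lines through the means of 3 arrays. At day 3 the USP2 shRNA arrays lie above the control arrays for FABP4 (4402 to 6166 against 728 to 1337) and FN1, and at day 2 below them for TYMS (798 to 936 against 2811 to 3489).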

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

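The tests of cells left as at day 0, of cell cycle genes at day 1 under other scalings and without 1 control array, and of a lasting difference between the derivatives were chosen after the results were seen, the ACTB covariate of the RNA quality test was added after the data but before its result was seen, and the others were set before.

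Of 69 genes named for the comparisons, 18 responded to PMA differently in the derivatives by the F test of the interaction, 8 with a positive and 10 with a negative largest term, against 284 of 14571 genes in all. Of the 18, 10 had been named because they passed this test, so their share says nothing. For 11 of the 18, FABP4, TNNT1, RBP4, AEN, SLC26A11, PNOC, SLC51B, PROC, HK3, MYBL2 and PLCD3, a group behind the term lay below the array median on all 3 arrays. The size of these terms depends on the offset of 16 and has no order. The largest term on any day was 2.73 for FABP4, 2.42 for RBP4, 2.32 for FN1, 2.07 for AEN and 1.92 for SLC26A11, each at day 3, and 2.69 for TNNT1, 1.96 for MYB and 1.43 for RHEX at day 1. It was -2.89 for PLCD3, -2.27 for MYBL2 and -1.92 for CENPM at day 2, and -2.10 for HK3, -1.86 for VAT1L, -1.65 for SLC51B and -0.94 for USP2 at day 1. At day 3 it was -1.99 for PROC, -1.74 for S100P and -1.17 for PNOC. A term holds the day 0 difference as well, which passed by itself for VAT1L and S100P.

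Among 63 tests of the 21 lists for a difference of the PMA response, 17 passed camera and 7 held with an estimated correlation. The cell cycle list had a median term of 0.29 at day 1 (4 of 30 higher, 8 adjusted over the list alone, adjusted p = 0.0186 with an estimated correlation), and -1.0 at day 2 (15 lower, 25 adjusted over the list alone, adjusted p = 5.75e-08). Its median term was -0.56 at day 3 (4 lower, 15 adjusted over the list alone, adjusted p = 1.64e-05). At day 1 the granule list had 0.83 (3 of 14 higher, 4 adjusted over the list alone, adjusted p = 0.0135), the phagocyte oxidase list 0.54 (3 of 6 higher, 4 adjusted over the list alone, adjusted p = 0.038) and the stress and amino acid response list -0.15 (3 of 19 lower, 3 adjusted over the list alone, adjusted p = 0.0135). Matrix and adhesion genes had 0.22 at day 2 (2 of 19 higher, 5 higher and 1 lower adjusted over the list alone, adjusted p = 0.0408). Outside the named genes, 34 of 6220 kept probe sets without a gene name differed between the derivatives over the 4 times, 17 higher and 17 lower.

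Some granule and cell cycle genes were higher at day 1 in USP2 shRNA cells. Array scaling was argued against by a granule median of 0.55 or more and 10 or more called cell cycle genes under quantile normalization and median centring. Without control day 1 replicate 3 the median was 0.4, with 10 cell cycle genes called, which argues against that array alone as the source. Control replicates 1 and 2 were not left out in this test. Without control replicate 1 the limma calls of CEBPE and RNASE2 ended (adjusted p = 0.269 and 0.131), so dependence on another control array stays open. Cells that had stayed as at day 0 could bring all abundant day 0 transcripts at the share of 2.77% that the median called gene needs. A first test on the median of 33 such genes (1.26%) had left this open. Called genes such as MS4A3, MYB and CDK1 were among the 33, so that median was not independent of the share needed. In 6 of the 33 genes the whole remaining level was below 0.5 of the 2.77%, with PRTN3 at 0.119%, ELANE at 0.314%, SERPINB10 at 0.82%, S100A8 at 0.833%, CTSG at 0.95% and CDCA7 at 1.01% of day 0. A smaller share of such cells, silencing of USP2, an off-target of this shRNA and a difference between the derivatives that came with their selection stay open as untested hypotheses.

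Cell cycle genes were lower at days 2 and 3 in USP2 shRNA cells. Array scaling was argued against, with a day 2 median of -0.84 or lower under quantile normalization and median centring. With the ACTB ratio as a covariate the day 2 median was -0.85. The log2 ratio was 1.55 ± 0.09 in USP2 shRNA cells and 1.69 ± 0.09 in control cells at day 2 (SD, n = 3). So small a difference left the covariate little to correct, and the test does not decide on RNA quality. The scaling and covariate values cover day 2 only. A later return of proliferation in USP2 shRNA cells may be a biological candidate explanation, and it cannot be separated from differences between 2 derivatives in growth or density, which were not measured here.

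The derivatives differed in 141 genes at day 0, where USP2 itself was low in both. In 114 of these, 80.9% (exact 95% interval 73.4 to 87), the brighter group lay above the array median on all 3 arrays, which leaves noise of dim probe sets open for part of them. Of the 141 genes, 54 (38.3%) kept their direction on all of days 1, 2 and 3. Random directions on independent days would give 12.5%. The days compare the same 2 derivatives and are not independent, so that share is not a fair baseline. A lasting difference between the derivatives and differences of the day may both contribute, and these values do not separate them.

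Each comparison of 3 with 3 arrays has 10 splits, too few for a share under 0.05, and in each of them 1 split, the real one, gave as many genes. The real count and the highest of the other splits were 141 and 27 at day 0, 386 and 336 at day 1, 296 and 1 at day 2 and 124 and 2 at day 3 for the derivatives. For PMA they were 8008 and 2, 8304 and 0, and 8186 and 0 in control cells, and 8110 and 1, 8349 and 0, and 8306 and 1 in USP2 shRNA cells. The other splits mix the true groups, so a real difference enters their spread and lowers their counts. For PMA, counts near 0 follow from this, and the size of these gaps supports nothing. The split with 336 genes at day 1 put control replicate 3 with USP2 shRNA replicates 2 and 3. These arrays had the lowest log2 ratios of 3' to 5' GAPDH control probe sets of that day, at -0.043, -0.028 and 0.033. The ratio was 0.087 and 0.076 in control replicates 1 and 2 and 0.110 in USP2 shRNA replicate 1. Differences in RNA quality between arrays of day 1 thus go along with this split, and their part in the day 1 calls was not tested. For the mean of 4 times (693 genes, highest other 102) and the interaction (284 genes, highest other 178), 100 of the possible within-day splits were run. In both, 1 of the 100, the real one, gave as many genes. For these 2 comparisons the rank of the real split makes chance assignment of arrays an unlikely cause but does not exclude it.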

How the results depend on the processing

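The ACTB covariate and the list tests without control day 1 replicate 3 were added after the data had been seen, and the other alternatives were planned. PMA counts stayed within 1.5 times of the reported ones under the alternatives run for them, which leave out the ACTB covariate, and the counts between the derivatives did not. With an offset of 64 the day 0 count was 90. With the mean over the probe sets of a gene the counts were 80 at day 0, 236 at day 1, 71 at day 3 and 187 for the interaction. Without the trend they were 80 at day 0 and 184 for the interaction. Array weights gave 1438 at day 1, 664 at day 2, 1233 for the mean of 4 times and 608 for the interaction, with the lowest weight (0.375) on control day 1 replicate 3. Fits of only the groups compared gave 24 at day 0, 123 at day 1, 661 at day 2 and 49 at day 3, and for the mean of 4 times and the interaction this is the same fit. The fewer arrays behind the spread belong to that alternative, and the cause was not tested for the others. The USP2 difference turned to 0.44 (exact permutation p = 0.243) with the dimmest USP2 probe set alone.

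Leaving out 1 array gave 89 to 151 genes at day 0 (lowest without control replicate 2), 204 to 1109 at day 1 (without control replicates 2 and 3), 171 to 201 at day 2 and 66 to 103 at day 3. It gave 538 to 1070 for the mean of 4 times and 228 to 544 for the interaction (both highest without control day 1 replicate 3). For PMA at days 1 to 3 the ranges were 7582 to 7843, 7879 to 7920 and 7771 to 7880 in control cells and 7729 to 7776, 7923 to 8040 and 7888 to 7942 in USP2 shRNA cells. The USP2 difference ran from -1.07 to -0.99. The lone pair of arrays left in a group is assumed to vary like the other groups.

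Replicate numbers did not pair the arrays. Over 84 pairs of arrays with the same number from different groups, the correlation of deviations ran from -0.0448 to 0.0863, none over 0.1. Of 24 arrays, 10 correlated best with an array of their own number. With the replicate block the counts were 144, 376, 284 and 121 on days 0 to 3, 662 for the mean of 4 times and 271 for the interaction, and the USP2 difference was -1.03 (exact permutation p = 0.000488). With the ACTB covariate they were 133, 441, 293, 131, 751 and 287. Of 231 tests of lists, 88 passed camera, 76 with an estimated correlation and 129 with fry. Of 206 called results for named genes, none changed direction in the fits that held them, which were 139 with the ACTB covariate, 179 with the filter of 12 arrays, 167 with only the groups compared and 206 with each other alternative. Calls were lost with the mean over probe sets (42), only the groups compared (36 of 167), no trend (20) and an offset of 1 (16), and in 208 of 1938 values without 1 array. Quantile normalization ended 1 and median centring 5 of these calls. Genes below the array median in a group have only a bound there, and the simulated recovery of 30% at a log2 change of 0.5 marks what 3 arrays per group can show.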

Other observations

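The lag test was planned before its result was seen, and the genes below were named by the rule for lists.

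Deubiquitinases other than USP2 differed between the derivatives as single genes, while their list did not pass camera on any day. UCHL1, a ubiquitin hydrolase of neurons and some tumours, was higher in USP2 shRNA cells at day 1 (1476 ± 126 against 853 ± 137), day 2 (1349.6 ± 109 against 666 ± 75) and day 3 (501 ± 51.8 against 280.1 ± 83.1). CYLD, which removes ubiquitin chains from NF-kappaB pathway proteins, was at 819 ± 245 against 481 ± 57.5 at day 1. At day 2 USP1, which acts on FANCD2 and PCNA, was lower at 2083 ± 50.3 against 2681 ± 99.4, as was the proteasome-bound USP14 at 6519 ± 216 against 8120.0 ± 137. Genes of the stress response list went both ways, with XBP1, a transcription factor of the unfolded protein response, lower at 2217 ± 23.2 against 3234 ± 469 at day 1. DDIT4, an inhibitor of mTORC1, was lower at 792 ± 102 against 1369 ± 51.9 at day 2 and HSPA5, an endoplasmic reticulum chaperone, higher at 13361 ± 758 against 10726 ± 390.4 at day 2.

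Of the lysosome list, LIPA was higher in USP2 shRNA cells at 4884 ± 92.9 against 3590.4 ± 71.7 at day 1 and 6160 ± 52 against 4634 ± 228 at day 2, as was NPC2, a cholesterol carrier, at 13761 ± 955 against 10441 ± 299.8 at day 3. The lysosome list as a whole had 1 of 24 higher and 1 lower at day 1 (2 and 2 adjusted over the list alone) and 2 higher and 1 lower at day 3 (2 and 1 adjusted over the list alone), with no camera call (adjusted p = 0.0778 at day 3). TIMP2, an inhibitor of matrix metalloproteinases, was lower over the 4 times (log2 -0.55 ± 0.08, adjusted p = 9.08e-05).

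One hypothesis was that USP2 shRNA cells lag behind control cells after PMA, so that their difference at day 1 follows control day 0 minus day 2 and their difference at day 2 follows control day 1 minus day 3. The correlations across 14571 genes, which are not independent replicates, were 0.021 and 0.102. Their sum of 0.123 had an exact permutation p of 0.015 (two-sided, 400 permutations, smallest possible 0.005), and lay between the bounds of 0.1 and 0.2 set in advance, so the test does not decide. Without the granule and cell cycle lists the correlations were 0.009 and 0.091.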
